A study of Schizosaccharomyces pombe with 3 samples.

How the data were processed

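Binding of the corepressor subunit Ssn6 was mapped in fission yeast, Schizosaccharomyces pombe, by chromatin immunoprecipitation on microarrays. Per the labels, cells carrying Ssn6 fused to green fluorescent protein grew to mid log phase in rich YES medium, crosslinked chromatin was precipitated with an antibody against the tag, and precipitated and input DNA from separate experiments were amplified, labelled and hybridised together. The series holds 3 arrays of 1 group, numbered here as replicates 1, 2 and 3 in the order of deposition. No untagged strain or mock precipitation was analysed here, and the meaning of a code in the sample titles was not given in the sources used here.

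Per the file headers and the labels' protocols, each array was scanned in 2 colours and quantified with TIGR Spotfinder, whose deposited files give spot intensity in whole numbers for a channel A and a channel B, the local background of each channel and a flag per channel. The software version was not given in the sources used here, nor whether background had been subtracted from the intensity values. The array held 22176 spots under 10248 names. Names fell into 5169 intergenic features, 4949 coding features, 95 other named features, 15 construct features such as Gfp, 7 negative-control names with 1624 spots and 13 other control names. These counts include 233 names that end in the word missing, 208 of them intergenic and 19 coding. Of the 3960 features tested below, 0 had such a name. Nearly every feature was spotted 2 times.

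The deposited series table held log10 values, described in the labels' protocols as median-normalised in GeneSpring by the authors. Set against the scanner values, these deposited log10 values were not ratios. On replicates 1 and 3, 97.68% and 96.03% of the comparable spots equalled, within 0.006, log10 of channel B's median intensity less its median background, after division by 1 constant per feature kind and spot number. On replicate 2 the deposited values matched channel A in the same way at 98.87% of spots and channel B at 2.70%. A floor of -2 stood at 6300, 1445 and 6733 spots of replicates 1, 2 and 3, and the medians of the deposited log10 values were 0.01, -0.04 and 0.02. Their scale and the channel they hold are therefore known, whereas the reason for the choice of channel is not.

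The direction of the ratio was not settled. The labels place input in Cy3 and immunoprecipitate in Cy5 on all 3 arrays but call this the general practice. They also state that dyes were not swapped, which goes against turning an array, and the files name channels A and B without dyes. Channel B over channel A on replicate 2 ran opposite to the other arrays. The log2 ratio used here therefore takes the channel of the deposited values as the numerator on each array, which is channel B on replicates 1 and 3 and channel A on replicate 2, and this numerator is called likely immunoprecipitate. That choice was made after the data were seen and departs from the planned test, which read 1 orientation on all 3 arrays from the labels. Values with channel B over channel A on all 3 arrays are given beside the ranked features, the counts of calls, the binding list, the class differences and the numbers of lists passed. Because the numerator rests on the authors' choice of channel, the sign of every ratio could also be turned as a whole.

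Log2 ratios were computed from integrated spot intensities without background subtraction. Spots with no positive intensity in either channel, which were also the spots with a rejection flag, were left out, each array was centred on the median of its log ratios, and the spots of a feature were averaged within an array. Features measured on all 3 arrays were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment). A feature with adjusted p under 0.05 was called enriched when its mean was above 0 and depleted when below 0. The moderated spread had 8.08 prior degrees of freedom and a prior SD of 0.55 on the log2 scale. The script was tested on simulated data with the fitted spread and 3960 features, 200 of them shifted. Shifts of 1, 2 and 3 on the log2 scale were recovered for 7.5%, 88.1% and 97% of the shifted features, and 5.88% of the calls were unshifted features. For the list test on 36 simulated combinations of list and feature kind, 1 list shifted by 0.5 gave an adjusted p of 1.08e-07, and 1 other list passed.

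The number of arrays limits the precision. The negative-control limit of a channel was the 95th percentile of all 1624 negative-control spots, rejected spots counting as 0. In the channel taken as immunoprecipitate it was 1959, 222.7 and 4452 mean pixel intensity units on replicates 1, 2 and 3, and 30.4%, 100% and 14.1% of the features with signal there lay above it. On replicate 2 this limit lies below 514.5, the median of the negative-control spots that gave signal, and in channel A of replicates 1 and 3, taken as input, it is 0. At a feature at or below the limit the immunoprecipitate signal itself is only an upper bound on that array. Of the tested features 37.0% on replicate 1 and 16.0% on replicate 3 lay above it. The median used for centring therefore rests largely on such signals too. The centred ratio of such a feature is not exact and has no known bound in either direction.

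Feature names were matched to the RefSeq annotation of assembly ASM294v3, used only for names, neighbours, chromosome position and GC content. Of the coding features 4781 matched a gene, and of the intergenic features 4916 did. The files name no genome build, so no coordinates are given. An intergenic feature was read as the region upstream of the gene in its name. The basis is that on replicate 2 features of divergent neighbours, which share an upstream gap, correlated at 0.63 across 1035 pairs, against 0.23 across 1077 convergent pairs. The same order held on replicate 1 (0.36 against 0.13) and on replicate 3 (0.45 against 0.10). Against the coding features of the neighbouring genes, intergenic features correlated higher on the upstream than on the downstream side on replicate 2 (0.47 against 0.27 and 0.42 against 0.27 for named genes on either strand), but not clearly on replicate 1 (0.095 against 0.093 and 0.089 against 0.074) and not on replicate 3 (0.071 against 0.074 and 0.076 against 0.166). The upstream reading is therefore an inference. Upstream regions are called divergent when the neighbouring gene points away from the named gene and tandem when it points the same way. Neighbours were taken from protein-coding, tRNA and rRNA genes only, so other noncoding RNA genes in a gap were passed over. Under this reading no feature is convergent, so the planned comparison with convergent regions could not be made, and regions near centromeres were not classed because the annotation used here marks none.

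The binding list followed the rank rule of the labels' protocols: spots were ranked as percentiles within each array and a feature was listed when the median percentile of all its spots reached 85. Class differences were tested per array with an exact sign-flip permutation test over the arrays, two-sided, whose smallest possible p with 3 arrays is 0.25, and calls per class with Fisher's exact test over features, which are not independent replicates. The 9 Fisher tests formed 1 family for adjustment. The 21 gene lists were fixed before the data were examined, from general knowledge of fission yeast genes. They were tested with camera (preset correlation 0.01), with an estimated correlation and with fry, separately for upstream and coding features, where at least 3 features were tested. With an estimated correlation camera also rests on the few residual degrees of freedom of these arrays. A call lost there therefore does not show that correlation between features was the cause. Genes were named by a rule also fixed before the data were examined. It takes the 15 intergenic and 10 coding features with the highest mean among those called and positive on every array, the 3 lowest of each class, up to 4 called members per list (2 where none was called), and all members of the lists of corepressor subunits and reported targets. One result that this rule selects is not reported here.

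Alternatives fixed beforehand were local background subtraction, normexp with offset 50, loess, centring by printing block or by feature class, a common scale, a filter on dim input (25th percentile), flags ignored, duplicate spots as separate values, an intensity trend with robust fitting, array weights, a threshold of 0.01, the deposited values and leaving out each array in turn. The deposited values hold 1 channel and no ratio. Tests on them compare brightness in that channel, not enrichment over input. Alternatives added after the data were seen were channel B over channel A on all 3 arrays, with and without loess, loess without replicate 2, separate centring of feature classes in the comparisons of classes, the difference of intergenic and coding features within 10 bins of input intensity, features measured on 2 or more arrays, and only features above the negative-control limit on all 3 arrays. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Per the labels, the 3 experiments were separate, without a statement of whether cultures were, so p-values measure the spread between these experiments.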

Results

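Ssn6 is a subunit of the Ssn6-Tup11/12 corepressor, a complex that represses transcription in fission yeast. Its distribution over the genome was measured in cells growing in rich medium on 3 two-colour arrays, each of which compared precipitated with input chromatin at intergenic and coding features. Replicate 2 gave the most complete data: 95.5% of its feature spots had signal in both channels, against 49.0% on replicate 1 and 37.7% on replicate 3. Intergenic spots were lost more often than coding spots, with 26.8% against 49.1% kept on replicate 3. Of the 20434 feature spots, 5622 on replicate 1 and 5623 on replicate 3 were rejected in both channels, and 4711 and 6993 in channel A alone. All 3 arrays together measured 3960 features, of which 1327 were intergenic, 2595 coding and 38 of other kinds. The paired spots of a feature correlated at 0.90, 0.95 and 0.89 across features on replicates 1, 2 and 3.

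The arrays were first set against each other. Read as channel B over channel A, the log2 ratios of replicates 1 and 3 correlated at 0.72 across features, whereas those of replicate 2 correlated at -0.48 with replicate 1 and at -0.54 with replicate 3. Channel A of replicate 1 correlated at 0.78 with channel B of replicate 2 and at 0.48 with its channel A, and channel A of replicate 3 at 0.68 and 0.37. Between replicates 1 and 3 channel A correlated at 0.79 and channel B at 0.47, so the agreement of their ratios need not come from channel B. With loess the correlation of these ratios was 0.58. The authors' deposited values likewise came from channel A on replicate 2 and from channel B on replicates 1 and 3. On this basis the channel of the deposited values was taken as the likely immunoprecipitate on each array. This choice was made after the data were seen and departs from the planned single orientation, under which 0 features passed the test. The labels' protocols state that dyes were not swapped, so the direction remains unsettled. Other scanner properties followed the channel rather than this assignment: spots lost in 1 channel alone lost channel A on replicate 2 as well (276 against 11 for channel B), and negative-control spots gave signal more often in channel B on every array (20.8%, 27% and 35.4%, against 1.5%, 5% and 2% in channel A). Turned this way, the pairwise correlations were 0.48, 0.72 and 0.54, with a mean of 0.58 across the 3960 features, which are not independent replicates. The median SD of a feature between arrays was 0.48 on the log2 scale.

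**Figure D1:**
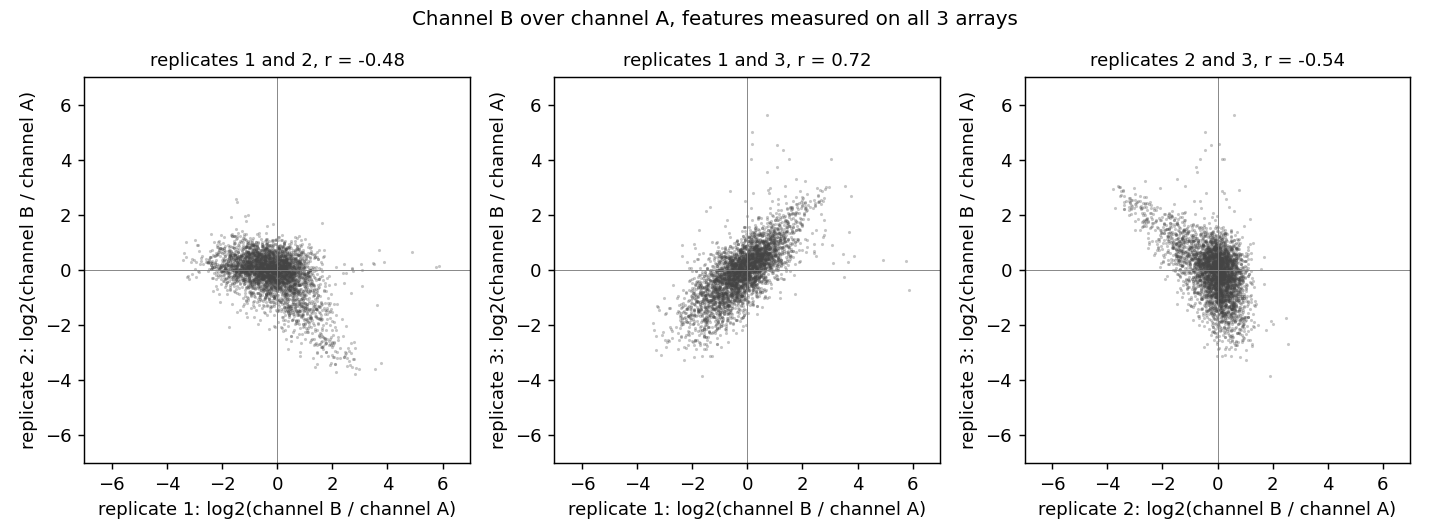
Log2 ratio of channel B over channel A, median-centred, for each pair of arrays; each point is one of the 3960 features measured on all 3 arrays. Replicates 1 and 3 rise together (r = 0.72), and replicate 2 runs opposite to both (r = -0.48 and -0.54).

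The highest ratio of an intergenic feature lay upstream of phf1. The region between phf1 and psk1, a divergent pair whose psk1 encodes an S6-type kinase, gave a log2 ratio of 3.28 ± 0.54 at the phf1 feature and 2.75 ± 0.76 at the psk1 feature (SD, n = 3 arrays, as for all values that follow). Upstream of str3, a transporter gene of the iron regulon, the ratio was 3.18 ± 0.53, a mean of 9.05-fold, and upstream of its neighbour shu1, which acts in heme acquisition, it was 2.70 ± 0.39. The region between fip1 and fio1, which encode the iron permease and the partner ferroxidase, reached 2.92 ± 0.50 and 2.74 ± 0.24 at its 2 features. Values of 2.88 ± 0.31 upstream of the glucosidase gene gto1, 2.83 ± 0.28 upstream of the galactose gene gal10, 2.83 ± 0.37 upstream of the ABC transporter gene abc3 and 2.73 ± 0.39 upstream of the phosphate transporter gene pho84 followed. The other intergenic features among the 15 highest were those of ef1-b (3.13 ± 0.37), mug24, which encodes an RNA-binding protein (3.03 ± 0.42), tna1 (3.00 ± 0.41), thf1, which encodes a tetrahydrofolate enzyme (2.80 ± 0.44) and SPAC25B8.12c (2.69 ± 0.12). All 15 features lay above the negative-control limit on all 3 arrays. That limit applies to the numerator of the ratio, and on replicate 2 100% of the tested features lay above it. The rule that chose the 15 requires a positive value on 3 of 3 arrays, and their limma adjusted p lay between 0.000786 and 0.0013. With channel B over channel A on all 3 arrays their means lay between 0.46 and 1.02 (limma adjusted p of 0.899 to 0.94), 0 of them stayed among the 15 highest, and the feature upstream of rpn10 stood first at 2.44 (adjusted p = 0.777).

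Fewer coding features stood high. SPBC887.16, an uncharacterised gene, had the highest mean of any feature, 3.40 ± 0.30 or 10.5-fold, and SPBC8E4.02c, annotated in the reference as the noncoding RNA prt2 beside pho84, had 3.19 ± 0.34. The coding features of mug114 (2.70 ± 0.88), SPAPB1A10.13 (2.66 ± 0.68), SPAC22F8.03c (2.61 ± 0.31), SPAC56F8.13 (2.54 ± 0.27), SPAC1F8.08 (2.46 ± 0.43), fip1 (2.38 ± 0.61), mug115 (2.37 ± 0.40) and tna1 (2.35 ± 0.62) completed the 10 highest, with adjusted p up to 0.00197. At 9 of the 10 the immunoprecipitate signal lay above the negative-control limit on all 3 arrays, the exception being tna1 on replicate 3. At the other end, the coding feature of the mitochondrial gene cox1 had the lowest mean, -2.47 ± 1.20, followed by rdp1 (-2.42 ± 1.23) and vrp1, the verprolin gene (-2.21 ± 0.98). The lowest intergenic features were those named for SPCC2H8.03 (-1.65 ± 0.66), tgp1 (-1.61 ± 0.96) and sce3 (-1.55 ± 0.56), the last 2 of them long intergenic features not assigned to a gene's upstream side. Of these 6, cox1 had immunoprecipitate signal above the negative-control limit on replicates 1 and 2 and the others on replicate 2 alone. Their means are therefore not exact and have no settled order. Every other depleted feature named here likewise lay at or below the limit on replicate 3. Of the 59 enriched features named here 15 did so too, so that their ratio there is not exact: the coding features of tna1 and meu10 and the upstream features of ght3, ght5, agl1, ptf1, isp5, psu1, pfl5, fnx2, prr1, tpi1, rpn502, hhf3 and Tf2-1. The 8 tested features named below that did not pass, those of ssn6, tup11, fbp1, inv1, ctt1, vph1 and vma2, lay at or below the limit on replicate 1, replicate 3 or both. Their means are not exact either. With channel B over channel A on all 3 arrays the means of the 10 coding features lay between 0.22 and 1.00, and those of the 3 lowest lay between -1.74 and -1.20 for coding and between -1.26 and -0.90 for intergenic features (limma adjusted p of 0.777 to 0.976). Of these, 0 of the 10 highest coding, 0 of the 3 lowest coding and 1 of the 3 lowest intergenic features kept such a rank.

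**Figure D2:**
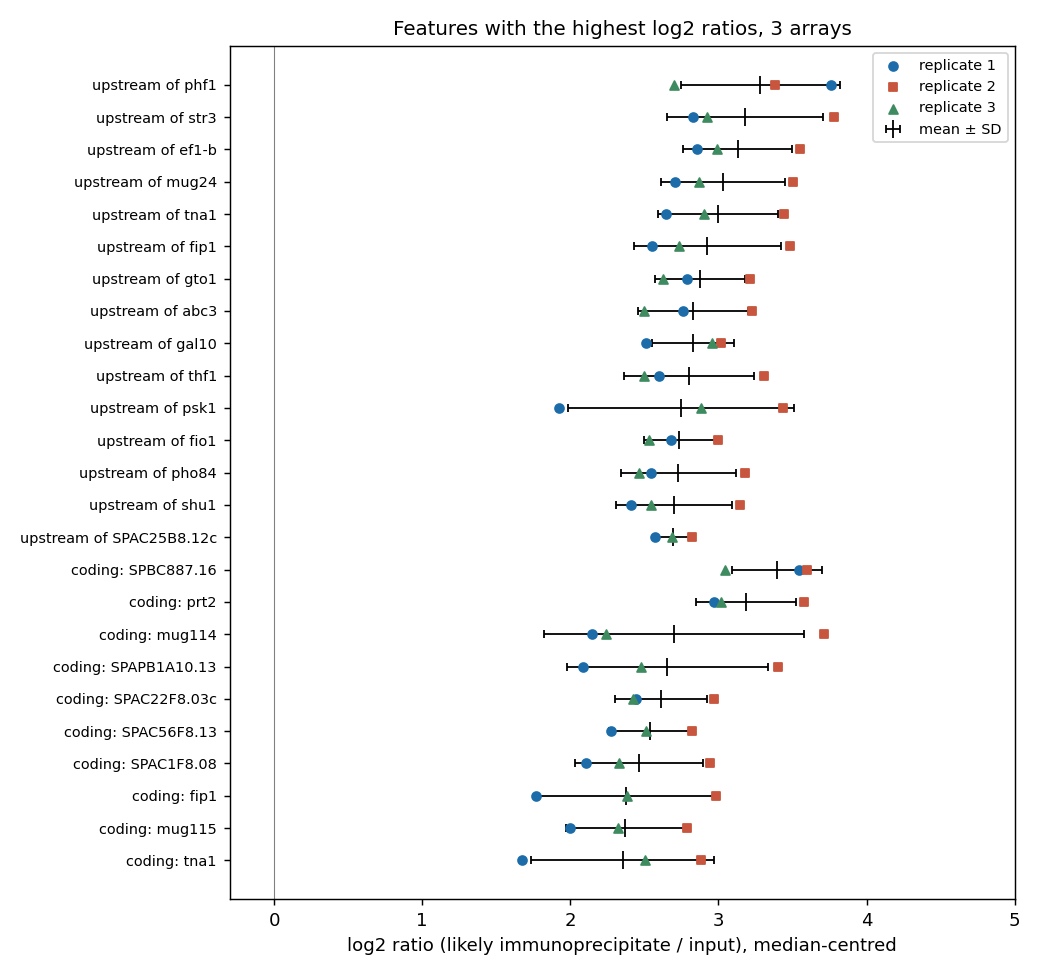
Log2 ratio, likely immunoprecipitate over input and median-centred, of the 15 intergenic and 10 coding features with the highest means; symbols are the 3 arrays and bars the mean ± SD. Means run from 2.35 to 3.40, and the rule that chose the features requires a positive value on 3 of 3 arrays.

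In total limma called 327 features enriched and 222 depleted among the 3960 tested. The enriched ones comprised 261 intergenic, 63 coding and 3 other features, and 326 of them were positive on all 3 arrays. The exception lay upstream of the proteasome gene rpn10, at 3.05, -0.23 and 4.03 on replicates 1, 2 and 3. Of the depleted features 204 were coding and 12 intergenic. With the classes centred separately, 152 intergenic and 110 coding features were enriched and 50 and 129 depleted. With channel B over channel A on all 3 arrays limma called 0 features in either direction, with 138 at an unadjusted p under 0.05. Without replicate 2 it called 331 enriched and 548 depleted features, which included 259 of the 327 and 211 of the 222. The deposited values also gave 0 calls, with 597 at an unadjusted p under 0.05. Immunoprecipitate signal lay above the negative-control limit on all 3 arrays at 11.8% of all tested features, at 190 of the 327 enriched and at 4 of the 222 depleted ones, whose call itself goes with low signal in that channel. Local background subtraction gave 135 enriched and 7 depleted features, and leaving out replicate 1 or 3 gave 58 or 9 depleted features.

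The rank rule of the series gave a binding list. Phf1, str3, ef1-b, mug24, gal10, gto1 and fip1 upstream features all had median percentiles above 99, and those of cta3 and pdc101 lay at 98.3 and 98.8. The list held 1106 of 9856 ranked features, of which 827 were intergenic and 266 coding, or 522 and 463 with percentiles taken within each class. It took in 319 of the 327 enriched features. In the top 15% of every array lay 250 features, 249 of them enriched in the same ratios, a count that the turning of replicate 2 raises. On replicates 1 and 3 alone 356 features did so, against 89.1 for independent arrays. These arrays were not independent in the denominator: their input channels correlated at 0.79 across features, and the channels taken as immunoprecipitate at 0.47. The excess over 89.1 can therefore come from shared input intensity and does not show reproducible enrichment. Of the listed features 334 were ranked on 1 array only, and with channel B over channel A on all 3 arrays 6 features lay in the top 15% of every array. The list then held 1003 features, of which 209 were among the 1106. The deposited values listed 873, of which 384 were shared, and without replicate 2 the list held 1196, of which 618 were shared.

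Intergenic features stood above coding features. Upstream features such as those of fip1 (2.92 ± 0.50) and tna1 (3.00 ± 0.41) stood above the coding features of the same genes (2.38 ± 0.61 and 2.35 ± 0.62) within each of the 3 arrays, by 0.55 ± 0.22 and 0.65 ± 0.30 (exact sign-flip permutation p = 0.25 for both). These differences were 0.21 ± 0.65 and 0.27 ± 0.78 with channel B over channel A, positive on 2 of 3 arrays. Both genes come from the highest features of each class, so they are examples and no test of the classes. The tna1 coding feature lay at or below the negative-control limit on replicate 3, so its difference there is not exact. Over the classes, the mean log2 ratio was 0.48 for intergenic and -0.27 for coding features, a difference of 0.74 ± 0.19 with the same sign on 3 of 3 arrays (0.87, 0.53 and 0.84). The shared sign follows from the turning of replicate 2, which gave -0.53 in channel B over channel A. The exact sign-flip permutation p of the turned differences was 0.25, the smallest that 3 arrays allow. Enriched calls made up 19.7% of intergenic and 2.4% of coding features (Fisher's exact test over features, p = 4.91e-73, adjusted p = 4.42e-72). With channel B over channel A the difference was 0.39 ± 0.80, and among features of like input intensity it was 0.35 ± 0.10. On replicate 2 it fell from 0.53 over features measured on all 3 arrays to 0.23 over all 4908 intergenic and 4845 coding features of that array.

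Regions between divergent genes were set against regions between tandem genes. The divergent regions of fip1 and fio1 and of gal10 and gal1 stood among the highest, as did the tandem regions upstream of str3, shu1 and tna1. The pho84 feature was classed as divergent with ecl3, but the noncoding RNA prt2 beside pho84 was not counted as a neighbour. Divergent features exceeded tandem features by 0.06 ± 0.09, positive on 2 of 3 arrays, with an exact sign-flip permutation p of 0.5. Enriched shares were 22.7% of 631 divergent and 17.9% of 457 tandem features (Fisher's exact test, p = 0.0585, adjusted p = 0.0752). Under the upstream reading a divergent gap can enter as 2 features, as 122 pairs did here, and a tandem gap as 1. All Fisher p-values of this comparison treat such paired features as separate and can be too small. The difference was larger with loess, at 0.14 ± 0.03 (177 of 631 against 88 of 457 enriched, Fisher's exact test, unadjusted p = 0.000975), and with normexp, at 0.14 ± 0.07 (p = 0.0222), both positive on 3 of 3 arrays, and it was -0.04 ± 0.11 with channel B over channel A. The unadjusted Fisher p was also 0.0118 with dim input removed, 0.000564 with features on 2 or more arrays, 0.0193 without replicate 1 and 0.0131 without replicate 3, against 0.111 without replicate 2 and 1.0 above the negative-control limit. The last of these filters selects on the numerator of the ratio and decides nothing. Where both features of a divergent gap were tested, as for fip1 and fio1, their means correlated at 0.69 across 122 pairs (0.33 with channel B over channel A), and both were enriched in 24 pairs. The reading of these features as upstream itself rests on the correlation of such pairs, so this is not independent evidence. Enrichment upstream also went with enrichment over the coding feature of the same gene: of 621 genes with both tested, 19 had both enriched, among them fip1, fio1 and tna1 (odds ratio 11.6, Fisher's exact test, p = 9.36e-09, adjusted p = 2.11e-08). This rests on the turned ratio: with channel B over channel A on all 3 arrays 0 features were enriched, so no such association can be formed.

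**Figure D3:**
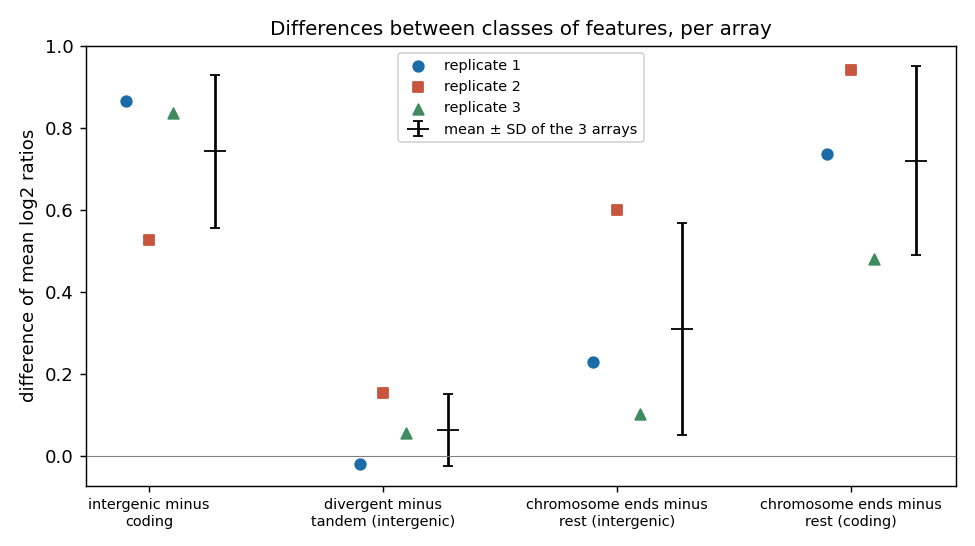
Difference of mean log2 ratios between classes of features on each of the 3 arrays (symbols), with the mean ± SD beside them. With replicate 2 turned, intergenic minus coding is 0.87, 0.53 and 0.84 on replicates 1, 2 and 3, and divergent minus tandem spans 0.

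The genes of the corepressor and its reported targets were examined first among the lists. Upstream of the reported targets, 5 of 6 measured features were enriched: fip1, fio1, the calcium ATPase gene cta3 (2.57 ± 0.73), the heat shock gene hsp9 (1.47 ± 0.37) and the siderophore transporter gene str1 (1.46 ± 0.31). The sixth, upstream of the invertase gene inv1, had 0.92 ± 0.48 (adjusted p = 0.0731). Adjusted over the list alone, 6 of 6 passed. Under the upstream reading the fip1 and fio1 features share a region, so these counts and camera's p-values upstream treat that region as 2 features. Camera gave an adjusted p of 0.00126 for this list upstream, and adjusted p = 0.453 with an estimated correlation. The list was drawn from general knowledge of this corepressor, which can include reports on these same data, so it is not independent evidence. Upstream features of frp1, ctt1 and gpx1 lacked a value on at least 1 array, with means of 2.86 and 1.11 on 2 arrays for frp1 and ctt1 and 0.65 on replicate 2 for gpx1. The upstream features of fbp1 and ste11 had no ratio on any array, and the array's own names for them end in the word missing. Their lack of a ratio therefore says nothing about binding there. Over coding features, fip1 and fio1 (1.60 ± 0.29) were enriched, fbp1 (0.78 ± 0.23), inv1 (0.53 ± 0.32) and ctt1 (0.03 ± 0.42) did not pass, and ste11, str1, gpx1, frp1, hsp9 and cta3 were not measured on all arrays, with values between -0.28 and 1.40. Camera's adjusted p for these coding features was 0.000374, and adjusted p = 0.699 with an estimated correlation, and 3 of 5 passed adjusted over the list alone. The coding features of the corepressor genes ssn6 (-0.41 ± 0.91) and tup11 (-0.39 ± 0.56) did not pass, and their upstream features were measured on replicate 2 alone, at 1.00 and 0.58. No feature for tup12 was matched.

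Iron uptake and storage genes were enriched at most of their measured upstream features. The array held 20 such features, and 3 of the enriched ones also belong to the reported targets. Those of fip1 and fio1 share a region under the upstream reading, which counts here as 2 features. Of 12 measured upstream features 9 were enriched, 9 also when adjusted over the list alone, and 12 were positive on all 3 arrays, led by str3, fip1, abc3 and fio1. Their mean was 1.87 against 0.52 for all 1143 upstream features tested (camera adjusted p = 0.000121, and adjusted p = 0.453 with an estimated correlation). Over the coding features of the same genes 4 of 12 were enriched, 4 adjusted over the list alone (camera adjusted p = 0.013, 0.0944 without replicate 2, and adjusted p = 0.699 with an estimated correlation). Among features above the negative-control limit on all 3 arrays, iron genes were the 1 list to pass camera, upstream with adjusted p = 0.0045 and over coding features with 0.0408 (adjusted p = 0.754 and 0.548 with an estimated correlation). That filter selects on the numerator of the ratio, so these passes decide nothing. The list of multidrug, ABC and MFS transporters had 7 of 13 upstream features enriched, 12 adjusted over the list alone (camera adjusted p = 0.00157, and adjusted p = 0.453 with an estimated correlation). Of these 7, 4 were iron genes such as str3, abc3 and str2 (1.75 ± 0.90), and mug24 encodes an RNA-binding protein. Over its coding features 1 of 10 was enriched, 0 adjusted over the list alone (camera adjusted p = 0.571). With the deposited values, which hold 1 channel and no ratio, camera gave an adjusted p of 0.0181, lost with an estimated correlation at 0.493.

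Genes of carbon metabolism formed 3 lists. Of the upstream features on the array, 8 of 15 were tested for glycolysis, 8 of 16 for glucose-repressed and 3 of 7 for hexose transporter genes. The last 2 lists share 2 enriched upstream features. All 8 measured upstream features of glycolysis and fermentation genes were enriched, 8 also adjusted over the list alone, including those of the pyruvate decarboxylase gene pdc101 (2.54 ± 0.55), the phosphofructokinase gene pfk1 (2.21 ± 0.58), tpi1 (2.08 ± 0.26) and the alcohol dehydrogenase gene adh1 (2.07 ± 1.16), with a camera adjusted p of 0.000373 and adjusted p = 0.453 with an estimated correlation. Their 8 coding features included 0 enriched, 0 adjusted over the list alone, with 6 above 0, yet passed camera (adjusted p = 0.013, and adjusted p = 0.699 with an estimated correlation). Upstream of glucose-repressed genes 5 of 8 were enriched, 7 adjusted over the list alone, among them gto1, ght3 (2.31 ± 0.39), agl1 (1.79 ± 0.43) and ght6 (1.55 ± 0.30), with camera adjusted p = 0.00451 and adjusted p = 0.453 with an estimated correlation. Their coding features had 1 of 11 enriched, ght3 (1.73 ± 0.40), 1 adjusted over the list alone (camera adjusted p = 0.00183, and adjusted p = 0.699 with an estimated correlation). Of the hexose transporter genes ght3, ght5 (1.38 ± 0.39) and ght6, 3 of 3 upstream features were enriched, 3 adjusted over the list alone (camera adjusted p = 0.029, and adjusted p = 0.453 with an estimated correlation), and 1 of 4 coding features was, 1 adjusted over the list alone (0.104). These coding features passed camera with loess (0.0267), with dim input removed (0.0457), without replicate 1 (0.0109) and with the deposited values of 1 channel (0.0108), where the adjusted p with an estimated correlation was 0.586, 0.854, 0.9 and 0.445. Camera thus passed 6 of 17 lists upstream and 5 of 19 over coding features, 0 of either with an estimated correlation, and with channel B over channel A on all 3 arrays 0 of either. The loss with an estimated correlation does not follow from correlation alone in every list. Among the lists that passed, that correlation ran from -0.18 for the coding features of the reported targets to 0.802 upstream of glycolysis genes. Where it is as high as 0.802, correlation can cost the call, and the camera p at the preset 0.01 can be too small. For iron coding features that correlation was 0.014, near the preset 0.01, yet camera's unadjusted p rose from 0.0028 to 0.0991. Fry, which tests a list against no change and not against other features, passed 12 and 1. Without replicate 2, 4 lists passed upstream and 2 over coding features: the calls were lost upstream for glucose-repressed genes (camera adjusted p = 0.0547) and hexose transporters (0.101) and over coding features for glucose-repressed, iron and glycolysis genes (0.0944, 0.0944 and 0.116). Upstream hexose transporters also did not pass with loess (0.0706) or the deposited values (0.0577), nor glucose-repressed genes with dim input removed (0.0926).

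The other lists that hold stress, nutrient and surface genes had enriched members without passing camera upstream. Stress response genes had 5 of 18 upstream features enriched, 5 adjusted over the list alone, with rsv2 (2.24 ± 0.35), the Hsp70 gene ssa1 (2.20 ± 0.59) and the glycerol phosphate dehydrogenase gene gpd1 (2.16 ± 0.67) after cta3 (camera adjusted p = 0.55). Over coding features 4 of 25 were enriched, 4 adjusted over the list alone with 2 depleted, and camera passed (adjusted p = 0.000737, and adjusted p = 0.699 with an estimated correlation). With the deposited values, which hold 1 channel and no ratio, the coding call was lost (0.309). The median of the upstream stress features, 0.35, lay below the 0.39 of all upstream features although the mean, 0.75, lay above the mean of all. Copper, zinc and phosphate uptake genes had 2 of 8 upstream features enriched, 3 adjusted over the list alone: pho84 and the acid phosphatase gene pho1 (1.82 ± 0.19), with camera adjusted p = 0.405, and 0 of 12 coding features, 0 adjusted over the list alone (0.891). Upstream of the amino acid and nitrogen permeases 4 of 7 were enriched, 5 adjusted over the list alone, namely isp5 (2.65 ± 0.43), cat1 (2.18 ± 0.98), fnx2 (1.46 ± 0.10) and isp4 (1.24 ± 0.64), with camera adjusted p = 0.0574, and 0 of 9 coding features were, 0 adjusted over the list alone (0.656). Cell surface genes had 6 of 14 enriched upstream, 6 adjusted over the list alone, led by psu1 (2.51 ± 0.59), cbf12 (1.96 ± 0.43) and pfl5 (1.69 ± 0.18), with camera adjusted p = 0.146. Of their 29 coding features 1 was enriched, meu10 (2.10 ± 0.51), and 3 were depleted, 1 and 4 adjusted over the list alone (0.826). Mating and meiosis genes had 4 of 14 upstream features enriched, 4 adjusted over the list alone, including isp5 and rsv2 (0.405), with 1 depleted in that adjustment, and over coding features 3 of 31 were enriched, meu10 among them, and 3 depleted (3 and 4 adjusted over the list alone), among them the meiotic cohesin gene rec8 (-2.11 ± 1.05), with camera adjusted p = 0.434. Transcription factor genes had 5 of 20 enriched upstream, 5 adjusted over the list alone, such as rsv2, prr1 (2.02 ± 0.39) and cbf12 (0.291), and 5 of 38 coding features depleted, 5 adjusted over the list alone, the lowest ntu1 (-1.87 ± 1.22), with camera adjusted p = 0.434. Some of these lists passed camera upstream in other settings: without replicate 1, stress, cell surface and permease genes (adjusted p = 0.0436 each), without replicate 3, permeases (0.00865) and transcription factors (0.0385), and with normexp, permeases (0.0488). With the deposited values, which hold 1 channel and no ratio, stress (0.000102), permease (0.00191) and copper, zinc and phosphate genes (0.00191) passed upstream, and over coding features permeases (0.00158), copper, zinc and phosphate (0.0019), cell surface (0.0188) and mating and meiosis genes (0.0311) did. With an estimated correlation these upstream calls were lost, with adjusted p from 0.648 to 0.672 without replicate 1, 0.621 without replicate 3, 0.432 with normexp and 0.707 with the deposited values, and the coding calls with adjusted p of 0.445 to 0.493.

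Genes of the translation and protein turnover machinery and the remaining lists did not pass camera where it was run on the ratios used here. Ribosomal protein genes had 5 of 44 enriched upstream, 5 adjusted over the list alone, the highest rpl2501 (1.82 ± 0.50), and their mean of 0.29 lay below the 0.52 of all upstream features (camera adjusted p = 0.271). Of 71 ribosomal coding features 1 was enriched and 5 depleted, 0 of either adjusted over the list alone, among them rpl2801 (-1.48 ± 1.28) and rpl502 (-1.47 ± 1.13), with camera adjusted p = 0.955. Proteasome genes had 2 of 7 upstream features enriched, 3 adjusted over the list alone, rpn10 with its opposite sign on replicate 2 and rpn502 (1.28 ± 0.10), with camera adjusted p = 0.827, and 2 of 17 coding features depleted, rpn12 (-1.35 ± 1.04) and pup3 (-1.09 ± 0.29), 0 adjusted over the list alone, with 0.667. The vacuolar ATPase list had 0 of 3 upstream and 0 of 7 coding features called (limma, adjusted p of 0.0507 for vph1 at -1.11 ± 0.66 and 0.189 for vma2 at -0.77 ± 0.98; camera adjusted p = 0.385 and 0.891), with 0 and 1 depleted adjusted over the list alone. Histone genes had 1 of 4 enriched upstream, hhf3 (1.09 ± 0.23), 1 adjusted over the list alone, and 0 of 8 coding features, where 1 enriched and 1 depleted passed adjusted over the list alone (camera adjusted p = 0.37 and 0.556). Of the G1/S genes suc22 was depleted over its coding feature (-1.66 ± 0.62), as 1 of 13, 1 adjusted over the list alone, with 0 of 2 called upstream (camera adjusted p = 0.826 over coding features). The coding median of the G1/S genes, -0.09, lay above the -0.28 of all coding features although their mean and camera's direction lay below, and the vacuolar ATPase coding median, -0.275, lay just above the -0.276 of all with its mean and camera's direction below. One upstream feature each was enriched for the wtf genes (wtf10, 1.11 ± 0.38, of 4; camera adjusted p = 0.44), the Tf2 retrotransposons (Tf2-1, 1.33 ± 0.45, of 1) and the thiamine genes (ptf1, 1.67 ± 0.19, of 2), and each also passed adjusted over the list alone. Their coding features, 12, 12 and 2 in number, included 0 called by limma, and adjusted over the list alone 0, 0 and 1, a depleted thiamine feature (camera adjusted p = 0.451 and 0.259 for the wtf genes and Tf2 elements). Tf2 coding features passed camera with loess (adjusted p = 0.00305) and with dim input removed (0.0268). With the deposited values, which hold 1 channel and no ratio, they passed camera too (adjusted p = 6.59e-11), as did histone (0.000696) and wtf genes (0.00996, and 0.00676 upstream). With an estimated correlation these calls were lost, with adjusted p of 0.586 with loess, 0.854 with dim input removed and 0.445 with the deposited values, or 0.707 upstream.

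**Figure D4:**
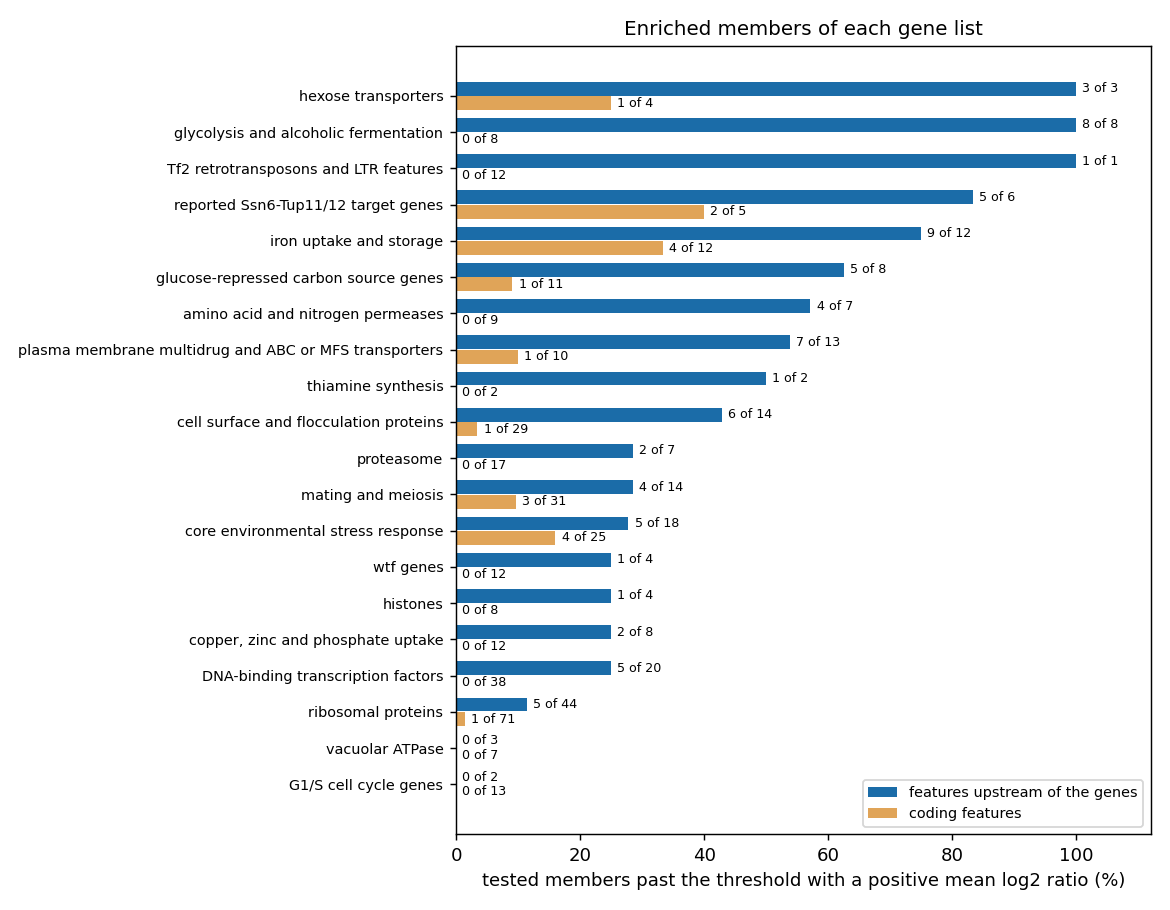
Percentage of tested members called enriched in each list, for features upstream of the genes and for coding features, with counts beside the bars; the corepressor list had no upstream feature tested. All 8 glycolysis and 9 of 12 iron upstream features are enriched, against 5 of 44 for ribosomal protein genes.

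Several of the highest features lay near chromosome ends. Upstream features of str3, shu1, ght3 and cat1 on chromosome I and of gal10, pho84 and pho1 on chromosome II belong to genes within 100 kb of an end in the reference. Intergenic features there exceeded the other intergenic features by 0.31 ± 0.26, with 18 of 53 against 222 of 1184 enriched (Fisher's exact test, p = 0.0116, adjusted p = 0.0209). With dim input removed this difference was 0.14 ± 0.22, positive on 2 of 3 arrays, with 7 of 35 against 110 of 637 enriched (Fisher's exact test, unadjusted p = 0.649), whereas it was 0.53 with normexp, 0.48 with loess and 0.16 without replicate 2, where the same test gave p = 0.052. Coding features, among them ght3, exceeded the rest by 0.72 ± 0.23, with 12 of 56 against 47 of 2443 enriched (p = 2.38e-09, adjusted p = 7.14e-09 by the same exact test). Both differences were positive on 3 of 3 arrays only with replicate 2 turned, which otherwise gave -0.60 and -0.94 (exact sign-flip permutation p of 0.25 as turned). With channel B over channel A they were -0.09 ± 0.45 and 0.09 ± 0.91, and among features above the negative-control limit on all 3 arrays -0.18 ± 0.14 and 0.16 ± 0.39, positive on 0 and 2 of 3 arrays. There 13 of 23 against 142 of 208 intergenic and 9 of 24 against 46 of 167 coding features were enriched, so neither call remained (Fisher's exact test, unadjusted p = 0.253 and 0.339). That filter selects on the numerator of the ratio, so it cannot decide whether the calls at chromosome ends hold.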

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

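The tests of a brightness trend, of sign patterns, of rejected input spots, of features of like input intensity and of other foreign sequences were chosen only after the results were seen.

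Gfp spots, which match the tag on Ssn6 and entered no comparison, gave signal above the negative-control limit at both duplicate spots on replicate 2 alone, with mean pixel intensities of 6728.5 in channel A and 6232.0 in channel B. Of 363 features of like brightness on replicate 2, 1 or 0.3% (exact 95% interval 0.0% to 1.5%) was rejected at every spot on both other arrays, which argues against spots of this brightness going undetected there. Signal on any foreign sequence is argued against as well, since 1 of 14 other construct features, KanMX-R, lay above the limit at both duplicate spots in both channels on replicate 2. Whether the arrays differ in strain, in probe or in labels was not tested, and no biological explanation was tested.

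Among the other constructs, with both duplicate spots required above the negative-control limit and single spots not counted, KanMX-R lay above it at 2917.5 in channel A and 2447.0 in channel B of replicate 2. Its 507.0 in channel A of replicate 1 and 1319.5 in channel A of replicate 3 also count as above, but the limit there is 0, and both lie below the medians of the negative-control spots that gave signal, 1311 and 2773. Those medians rest on 25 and 33 of 1624 negative-control spots, so they give no background level. KanMX-R gave signal at both duplicate spots in both channels on all 3 arrays. By the rule of both duplicate spots Pho4_BD-R lay above the limit in channel A of replicate 2, at 725.0, and Sc_GCN5A_69 in channel B of replicate 2, at 1065.5.

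Replicate 2 ran opposite to replicates 1 and 3 in channel B over channel A. A trend of the ratio with brightness is argued against as the whole cause, because the higher of the correlations with replicate 2 was still -0.586 after loess. Swapped channels on replicate 2 may explain the pattern but were not decided by the test written beforehand: features that had lost channel A on both other arrays should then lie low in channel B over channel A on replicate 2, and the area under the curve was 0.53 (0.445 after loess), where 0.5 is no difference. For the turned fit, 1 of the 4 sign patterns of the arrays, the one used, gave as many features past the threshold, 549 against at most 0 for the others, and 4 patterns are too few for a share under 0.05. The labels state that dyes were not swapped, whereas exchanged samples or channels stay open and a true difference between the experiments was not tested.

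Intergenic features lay above coding features. Base composition is argued against within a window of 36% to 39% GC, where the difference was 0.997 against 0.797 over the 3642 features with a GC value. That window held 97 intergenic and 853 coding features. Median GC was 32.3% for intergenic and 39.4% for coding features, so it covers the GC-rich end of the intergenic ones. GC was taken from whole genes and gaps in the reference, not from the spotted probes. An immunoprecipitate channel near the negative controls may account for part of the difference, which was 0.354 ± 0.10 among features of like input intensity (0.264, 0.467 and 0.331 on replicates 1, 2 and 3, against 0.866, 0.528 and 0.838 over all), although matching on the denominator of the ratio can itself lower it. Among features above the limit on all 3 arrays it was 0.781 ± 0.07, which decides nothing, since that filter selects on the numerator. Loss of features with rejected input may also account for part, because on replicate 2 the difference was 0.226 over all features it measured, against 0.528 over those measured on all 3 arrays.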

How the results depend on the processing

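The alternatives with channel B over channel A, with loess without replicate 2, with features on 2 or more arrays, with features above the negative-control limit, with features of like input intensity, and separate class centring in class comparisons were chosen only after the data were seen. Of the features with immunoprecipitate signal, 30.4% on replicate 1 and 14.1% on replicate 3 lay above the negative-control limit, and 3 arrays limit all tests. With channel B over channel A on all 3 arrays 0 features were enriched and 0 depleted (limma, 138 at an unadjusted p under 0.05), also with loess (0 and 0, with 31), and 0 upstream and 0 coding lists passed. Agreement between arrays became -0.1, or -0.208 with loess. The top 15% of every array then held 6 features, intergenic minus coding was 0.392 (0.233 with loess) and divergent minus tandem -0.039 (0.036 with loess). The difference at chromosome ends was -0.09 for intergenic (0.103 with loess) and 0.092 for coding features (0.217 with loess). Opposite signs arose for ctt1 (-0.312) and upstream of isp4 (-0.071), adh1 (-0.019) and str2 (-0.012), and with loess for tna1 (-0.044), ssn6 (0.28), fbp1 (-0.18), ctt1 (-0.087) and upstream of isp4 (-0.009).

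With the deposited values, which hold 1 channel, 0 features were enriched and 0 depleted (limma, 597 at an unadjusted p under 0.05), agreement was 0.254, intergenic minus coding 0.272, the intergenic difference at chromosome ends 0.688, and 13 coding lists passed. Intergenic minus coding cannot test the class difference here, since these values match the channel only after division by a constant per feature kind. Signs turned for the long intergenic features of tgp1 (1.046) and sce3 (0.354) and the coding features of cox1 (0.144), ssn6 (0.354), tup11 (0.26), fbp1 (-0.022), ntu1 (0.952), rpl2801 (0.205), rpn12 (0.166), vma2 (0.066) and suc22 (0.277).

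Enriched and depleted counts, 327 and 222 as reported, were 135 and 7 after local background subtraction, 203 and 114 on a common scale, 551 and 736 with array weights and 140 and 19 at an adjusted p under 0.01, where the threshold itself lowers them. Enriched features numbered 198 with dim input removed, and depleted features 345 with duplicate spots kept separate, 356 with trend and robust fitting, 137 with loess without replicate 2 and 12 above the negative-control limit, where fewer features were tested. Above that limit the chromosome-end difference was -0.18 for intergenic and 0.16 for coding features, and 1 upstream and 1 coding list passed, but the limit selects on the numerator of the ratio. With normexp, intergenic minus coding was 1.212, the coding difference at chromosome ends 1.284 and ctt1 -0.027. Ctt1 was -0.117 with array weights, and ssn6 was 0.198 with loess without replicate 2. Percentile limits of 90 and 95 listed 710 and 334 features. An estimated correlation, which leaves camera few residual degrees of freedom, left 0 upstream and 0 coding lists, and fry, which tests against no change, gave 12 and 1. Among features of like input intensity, intergenic minus coding was 0.354.

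Leaving out each array gave 209 to 331 enriched and 9 to 548 depleted features, 1101 to 1196 listed features with 349 to 392 in the top 15% of every array, 4 to 9 upstream and 2 to 6 coding lists, and differences of 0.651 to 0.853 for intergenic minus coding, 0.022 to 0.067 for divergent minus tandem, 0.164 to 0.409 for intergenic and 0.611 to 0.851 for coding features at chromosome ends. Ssn6 ranged from -0.829 to 0.07, the latter without replicate 1, and ctt1 from -0.209, without replicate 2, to 0.179. Where no construction is named, the cause was not tested. Flags ignored changed nothing, since rejected spots had no signal. Of the 81 named features tested, loess kept 80, block centring 78, leaving out replicate 1, 2 or 3 69, 76 or 57, and channel B over channel A 7 on the same side of the threshold with the same sign, as did local background subtraction for 50 of 74 and the deposited values for 4 of 80.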
